A study of Mus musculus with 23 samples.

How the data were processed

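RNA was measured in 23 liver samples of male C3H mice with Affymetrix 3' in vitro transcription arrays, 1 array per sample. Per the labels, the mice were wild type or carried a hepatocyte-specific knockout of Ctnnb1, the gene of beta-catenin. In the knockout, Cre recombinase under the albumin promoter removed the part of Ctnnb1 between loxP sites that flank exons 3 and 6. Mice of both genotypes received 0.05% phenobarbital in the diet for 12 weeks or a diet without it. The labels also name water as the vehicle of the controls, a point that the treatment description does not mention. The labels number the replicates of each group but do not state that each is a separate animal, so the p values measure the spread between these samples.

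The deposited values are log2 signals per probe set, which the authors computed with robust multi-array averaging (RMA) in the R package affy. Their versions, and which arrays were normalized together, are not stated. Values were used as deposited, without a further log or scaling step. Between the 23 arrays, the median over all probe sets ranged from 5.09 to 5.14. The table held 45037 probe sets: 34945 were assigned to exactly 1 gene in the platform annotation, 932 to several genes and 9160 to none. Current gene symbols were taken from the GRCm38.p6 gene table through the Entrez identifier for 34741 probe sets, and 204 kept the platform's symbol.

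Each of 18193 genes was represented by the probe set with the highest mean over all arrays, among those assigned to that gene alone. A gene was tested if it exceeded the 40th percentile of all probe sets of an array in at least 4 arrays, which left 11579 genes and removed 6614. A linear model with 1 mean per group was fitted to all 23 arrays with limma 3.58.1 in R 4.3.3, with moderated variances. The 5 comparisons were the phenobarbital effect in wild type and in knockout, knockout against wild type without and with phenobarbital, and the interaction. The interaction is the phenobarbital effect in knockout minus that in wild type. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 changes are given with their standard error (SE), and levels as log2 mean ± SD per group.

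A total of 31 gene lists was fixed in advance, and 29 had the 5 measured members that a test required. The lists comprised beta-catenin-dependent perivenous genes and Wnt targets, periportal genes, phase I enzymes, conjugation enzymes, transporters and targets of the constitutive androstane receptor (CAR). Further lists covered the imprinted Dlk1-Dio3 region, bile acids, cholesterol synthesis, lipogenesis, fatty acid oxidation, glucose metabolism, urea and ammonia, Nrf2 targets, proliferation, and p53 and growth arrest. The others covered the acute phase, interferon, the unfolded protein response, the circadian clock, male-biased and female-biased genes, and fetal and tumour genes. Markers of macrophages, lymphocytes, neutrophils, cholangiocytes, stellate cells and scar, endothelium, blood and other tissues were also fixed. Lists were tested with limma's camera at a preset correlation of 0.01, with p values adjusted over all 145 list and comparison pairs. Camera with an estimated correlation and fry were run beside it. Member counts are given over all genes tested and adjusted over the list alone. The lists share members, so a gene can count in several of them. Gsta2, Gstm1 and Ephx1 were in the CAR and Nrf2 lists, and Cyp2b9 and Cyp2b13 in the CAR and female-biased lists. The perivenous list shared Glul, Rhbg, Slc1a2 and Oat with urea and ammonia, and Cyp7a1, Cyp27a1 and Slco1b2 with bile acids.

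Named genes followed a fixed rule. It took Ctnnb1, and per comparison the 8 largest rises and the 8 largest falls among changed genes without overlap between the arrays of both groups. No such condition applied to the interaction, and placeholder names were left out. For lists past the camera threshold, or with at least 3 changed members, the rule added up to 3 changed members with the largest change. A fixed set of marker genes was given in every comparison. Of that set, Gls2 had no probe set assigned to it alone and is not analysed here. The lists, the rule, the model and a first set of alternative settings were chosen before the data were examined.

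Differences of list means between groups were tested with exact two-sided permutation tests, which enumerated 792 splits without phenobarbital and 330 with it. The alternative settings were no filter and a filter at the 60th percentile, quantile normalization, median centring, the mean of probe sets, every probe set, a trended and robust prior and a 2-fold minimum. Array weights, a block for the replicate number, only the compared groups and leaving out each array in turn were run too. Chosen after seeing the data were 1 weight per group, a fit without the 3 knockout control arrays whose weight, estimated from the same data, was under 0.5, and a covariate for the level of non-hepatocyte markers. The fit without the 3 arrays kept all knockout phenobarbital arrays. Ranges of adjusted p over all alternatives were taken without regard to the direction of the change. The procedure was tested on simulated data with 200 changed genes. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Probe sets assigned to several genes or to none were left out, and for arrays their number limits the precision.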

Results

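Liver RNA of male mice was profiled on 23 arrays in 4 groups: wild type without phenobarbital (n = 5), wild type with phenobarbital (n = 4), Ctnnb1 knockout without phenobarbital (n = 7) and knockout with phenobarbital (n = 7). Phenobarbital is a barbiturate that activates CAR in hepatocytes and promotes liver tumours in mice, and the C3H strain is sensitive to that promotion. Beta-catenin is the effector of canonical Wnt signalling and sustains the perivenous programme of hepatocytes around the central vein. The spread between arrays was larger in knockout liver. The median SD per gene was 0.12 and 0.0885 in wild type without and with phenobarbital, against 0.16 and 0.135 in knockout. The lowest correlation between arrays of a group was 0.987, 0.994, 0.928 and 0.959 in the same order. The number of arrays limits the precision of every comparison.

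The first comparison asked what 12 weeks of phenobarbital changed in wild-type liver. Cyp2b10, a cytochrome P450 and the classical CAR target (GRCm38.p6 chromosome 7, 25897658 to 25926624), rose from 5.68 ± 0.39 to 12.64 ± 0.048 (log2 mean ± SD, n = 5 and 4; log2 change 6.96, SE 0.37, adjusted p = 1.94e-11). Further cytochromes P450 rose with it: Cyp2c65 by 6.83 (SE 0.29), Cyp2b9 by 5.04 (SE 0.65), Cyp2c55 by 4.54 (SE 0.37) and Cyp2b13 by 4.46 (SE 0.52). In every wild-type control array Cyp2c65 (mean 3.267) and Cyp2b9 (4.011) were below the filter's level, the 40th percentile of the array, which averaged 4.56, so the size of their changes is uncertain. Set against that level they were 5.54 and 4.49. Of 4 measured RNAs of the imprinted Dlk1-Dio3 region on chromosome 12, 2 rose as well, also adjusted over the list alone. Meg3 (109540996 to 109571729) reached 10.87 ± 0.094 from 8.79 ± 0.38 (log2 change 2.07, SE 0.12, adjusted p = 1.87e-10), and 9 of its 11 probe sets rose. Rian (109603945 to 109661716) rose by 1.55 (SE 0.20, adjusted p = 3.59e-05), with all 4 of its probe sets higher.

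Outside the cytochromes P450, the genes named for the largest rises in wild type were the nebulin-related Nebl (5.20, adjusted p = 7.9e-14), the chemokine receptor Ackr3 (4.15, adjusted p = 1.41e-06) and the oestrogen sulphotransferase Sult1e1 (4.09, adjusted p = 1.1e-08), which was below the filter's level in the controls (3.22 against that level). The largest fall was that of the immediate-early transcription factor Egr1, from 10.76 ± 0.32 to 6.90 ± 0.45 (log2 change -3.85, SE 0.45, adjusted p = 7.6e-06). The trefoil factor Tff3 (-2.60, adjusted p = 0.00364), Dnaic1 (-2.30, adjusted p = 7.09e-07) and the retinol dehydrogenase Rdh16f2 (-2.20, adjusted p = 0.000126) fell too. Enho, which encodes adropin, Nipal1 and Tspyl4 fell, with log2 changes of -1.98, -1.77 and -1.68 (adjusted p = 0.000184, 0.00531 and 0.000212). The transcriptional repressor Bcl6 fell (-2.52, adjusted p = 0.0388). Its call ended without any 1 of wild-type control replicates 1 to 4 or of phenobarbital replicates 1 to 3, with adjusted p from 0.0528 to 0.138 (over all alternatives 0.00408 to 0.138). No array of the phenobarbital group overlapped with a control array for any of these genes.

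Of 37 measured CAR targets, 20 rose and 0 fell, against 27 that rose when adjusted over the list alone (camera adjusted p = 4.1e-32). Of 50 phase I enzymes, 17 rose and 0 fell, against 23 and 1 adjusted over the list alone (adjusted p = 8.62e-16). Of 39 conjugation enzymes, 10 rose, against 12 adjusted over the list alone (adjusted p = 8.06e-07). They included the sulphotransferase Sult1c2 (2.12, SE 0.23) and the glutathione transferases Gstt3 (1.90, SE 0.27) and Gstm1 (1.47, SE 0.28). With an estimated correlation, the adjusted p of these 3 lists was 5.48e-06, 0.0104 and 0.0495. They passed it in both genotypes, and of all 145 list tests only the perivenous list did so besides, in both comparisons of the genotypes. Among 20 Nrf2 targets 6 rose, with Gsta2 at 1.09 (SE 0.26), and 1 fell (7 and 1 adjusted over the list alone). That list had a camera adjusted p = 5.67e-05 and an adjusted p = 0.388 with an estimated correlation. Among 25 lipogenic genes 5 rose (7 adjusted over the list alone), led by the lipase gene Pnpla3 (2.03, SE 0.43) and Thrsp (1.30, SE 0.27). The camera adjusted p was 0.000238, and the adjusted p = 0.547 with an estimated correlation.

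Of 19 female-biased liver genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), and Cyp2b9, Cyp2b13 and Sult1e1 were those with the largest change (camera adjusted p = 0.00453, and adjusted p = 0.476 with an estimated correlation). Among 24 transporters the efflux pumps Abcc4 (3.08, SE 0.41) and Abcc3 (1.28, SE 0.15) rose with 1 other. The list as a whole stayed at an adjusted p = 0.298, with a median change of -0.0606 and a mean of 0.17. Of 21 genes of urea and ammonia metabolism 4 fell (8 adjusted over the list alone), with a camera adjusted p = 0.000105 and an adjusted p = 0.459 with an estimated correlation. Of 31 perivenous genes 2 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.101). Tnfrsf19 was the member with the largest rise (1.62, SE 0.18). The glutamate transporter Slc1a2 (-1.15, SE 0.21) and the R-spondin receptor Lgr5 (-1.01, SE 0.15) fell.

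Several markers fixed in advance did not pass the test in wild type. Cyp2c29 went from 13.53 ± 0.12 to 13.89 ± 0.068 (adjusted p = 0.822) and Cyp3a11 from 14.26 ± 0.064 to 14.41 ± 0.024 (adjusted p = 0.084). Both stood near the top of the array's range, whose highest value was 14.92, before treatment. Glutamine synthetase Glul (-0.66, adjusted p = 0.278), Cyp1a2 (0.69, adjusted p = 0.054), Oat (-0.77, adjusted p = 0.0799) and Axin2 (-0.082, SE 0.12) did not pass either. Nor did Cyp2e1 (0.017, 0.993), Cyp2f2 (0.034, 0.884), Cyp7a1 (-0.22, 0.862), or the cell cycle genes Ccnd1 (-0.39, 0.866) and Mki67 (0.47, 0.787). For Cyp2c29, Cyp3a11, Glul, Cyp1a2 and Oat, however, the arrays of both groups did not overlap. With only wild-type arrays fitted, adjusted p was 0.0104, 0.0976, 0.000588, 0.000339 and 0.0292 (over all alternatives 0.00544 to 0.91, 0.0112 to 0.197, 0.000588 to 0.473, 0.000339 to 0.14 and 0.00702 to 0.186). So 4 of these 5 passed without the knockout arrays in the fit. Of 24 proliferation genes 0 changed, also adjusted over the list alone (camera adjusted p = 0.0905, fry mixed adjusted p = 0.473).

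Phenobarbital changed 577 of 11579 genes in wild type, 279 up and 298 down. At least 2-fold changes were found for 63 rising and 24 falling genes. In 1522 of the 11579 genes the arrays of both groups did not overlap, which chance gives for 1.6%, and 508 of them were changed. The number of changed genes fell to 325 without phenobarbital replicate 3 and to 374 without phenobarbital replicate 1. It rose to 998 when only the arrays of wild type were fitted.

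**Figure D1:**
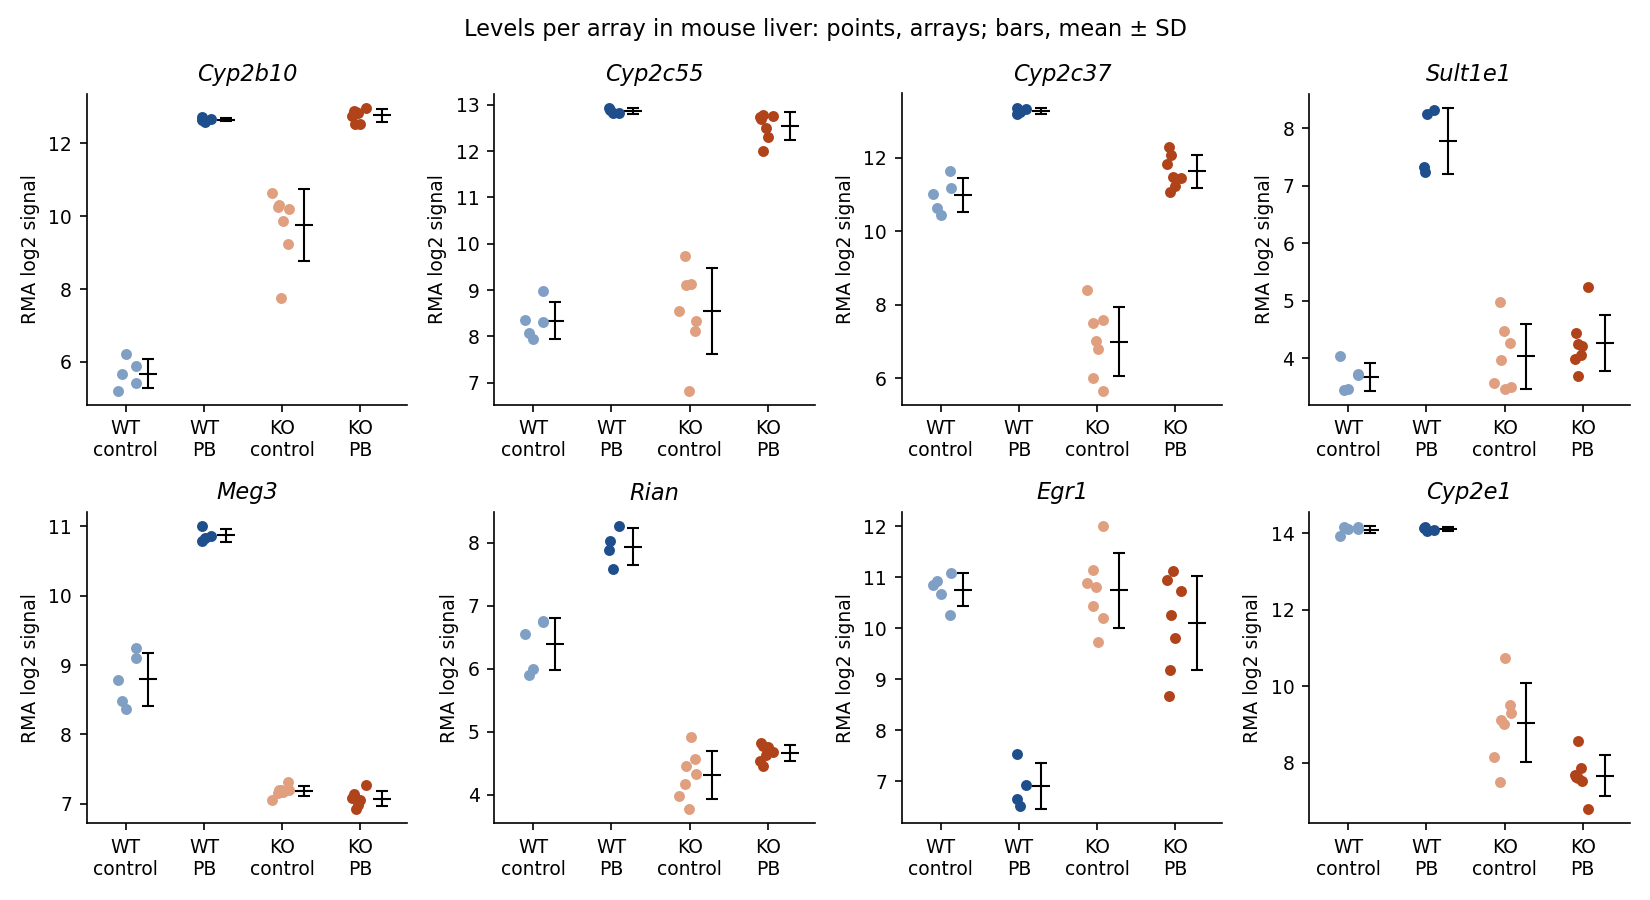
Levels of 8 genes in every array (RMA log2 signal on the y axis) for wild type (WT) and knockout (KO) livers without (control) and with phenobarbital (PB). Points are arrays and bars give mean ± SD; Meg3 averaged 10.87 in wild type with phenobarbital and 7.08 in knockout with phenobarbital.

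The same treatment was then compared in livers with the hepatocyte knockout. Cytochromes P450 of the 2c family rose most: Cyp2c37 from 6.99 ± 0.94 to 11.64 ± 0.45 (n = 7 and 7; log2 change 4.64, SE 0.32, adjusted p = 4.57e-09), Cyp2c55 by 3.999 (SE 0.29) and Cyp2c65 by 3.997 (SE 0.23; 2.55 against the filter's level, below which it was in all knockout controls). Cyp2c54 rose by 3.24 (SE 0.55) and Cyp2c50 by 2.997 (SE 0.43). Cyp2b10 rose from 9.75 ± 0.98 to 12.76 ± 0.17 (log2 change 3.01, SE 0.30, adjusted p = 2.18e-06). The aryl hydrocarbon receptor target Cyp1a2 rose by 1.28 (SE 0.16, adjusted p = 7.15e-05), and Nebl by 2.37 (SE 0.16). Several of these P450 genes are close paralogs whose probe sets can share signal.

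Falls were smaller. The secreted ribonuclease Rnase4 (-0.94, adjusted p = 0.000736), the cohesin loader Nipbl (-0.77, adjusted p = 6.99e-09) and the chromosome maintenance gene Smc6 (-0.55, adjusted p = 9.76e-06) had lower levels in all phenobarbital arrays than in any control. The same held for Zbed6 (-0.80, adjusted p = 7.15e-05), Tpm2 (-0.74, adjusted p = 0.00217), Sntb2 (-0.70, adjusted p = 0.000581), Zfp945 (-0.50, adjusted p = 0.00721) and Cldnd1 (-0.47, adjusted p = 0.00268). The Tpm2 and Cldnd1 calls ended when the probe sets of a gene were averaged (adjusted p = 0.0928 and 0.234; over all alternatives 0.000878 to 0.0928 and 0.000809 to 0.234). The remaining perivenous signal of Cyp2e1 fell further, from 9.05 ± 1.03 to 7.67 ± 0.53 (adjusted p = 0.0227), as did Gulo (-0.90, adjusted p = 0.00715). When only knockout arrays were fitted, their adjusted p was 0.125 and 0.0637 (over all alternatives 0.000816 to 0.125 and 0.0013 to 0.0637). The myofibroblast marker Acta2 fell (-1.005, adjusted p = 0.0194), but its adjusted p was 0.0697 without knockout control replicates 2, 6 and 7 and 0.0818 with only knockout arrays (over all alternatives 0.00334 to 0.0818). Arrays of both groups overlapped for Cyp2e1, Gulo, Acta2, and also for Gstt3 and Oat.

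Of 37 CAR targets 18 rose (28 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.62e-28, and 1.07e-05 with an estimated correlation). Of 50 phase I enzymes 18 rose and 3 fell (28 and 4 adjusted over the list alone; adjusted p = 1.27e-16, and 0.00919 with an estimated correlation). Of 39 conjugation enzymes 13 rose (17 rose and 1 fell adjusted over the list alone; adjusted p = 3.23e-11, and 0.00664 with an estimated correlation). Among them were Gsta2 (1.22, SE 0.21), Gstt3 (1.14, SE 0.21) and Sult1c2 (1.01, SE 0.18). Of 20 Nrf2 targets 5 rose (8 adjusted over the list alone), among them the epoxide hydrolase Ephx1 (0.84, SE 0.12), also in the CAR list. The list's camera adjusted p was 6.45e-08, and the adjusted p = 0.146 with an estimated correlation.

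Meg3 (-0.11, adjusted p = 0.658) and Rian (0.35, adjusted p = 0.291) did not pass the test in knockout, and 1 of 11 Meg3 probe sets and 0 of 4 Rian probe sets rose. Cyp2c29 (1.45, adjusted p = 0.0586), Glul (-0.25, 0.682), Axin2 (-0.014, 0.963), Cyp2f2 (0.15, 0.145), Cyp7a1 (-0.089, 0.925), Ccnd1 (0.49, 0.734) and Mki67 (0.02, 0.99) did not pass either. Cyp2c29 and Ccnd1 passed without knockout control replicates 2, 6 and 7 (adjusted p = 0.00329 and 0.023; over all alternatives 0.00329 to 0.213 and 0.000533 to 0.873). Oat fell (-0.77, adjusted p = 0.0349), and its adjusted p was 0.0511 to 0.076 without any 1 of knockout control replicates 1, 2, 6 and 7 or phenobarbital replicates 1, 2, 3 and 6. It was 0.147, with a log2 change of -0.5365, without knockout control replicates 2, 6 and 7, and 0.0974 with only knockout arrays (over all alternatives 0.0164 to 0.147). Cyp3a11 rose by 0.15 (adjusted p = 0.0411). That call ended, with adjusted p from 0.0514 to 0.0925, without any 1 of knockout control replicates 3 to 5, knockout phenobarbital replicates 1, 2 and 4 to 7, or wild-type phenobarbital replicates 1, 3 and 4, and it was 0.132 with only knockout arrays (over all alternatives 0.0083 to 0.132).

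In knockout, 325 genes changed, 170 up and 155 down, and 17 rose and 5 fell at least 2-fold. After median centring 68.7% of the changed genes were higher, and 66.8% after quantile normalization, against 52.3% as deposited. In 128 of all genes the arrays did not overlap, which chance gives for 0.058%, and 107 of them were changed. The count was 212 without knockout phenobarbital replicate 1, 829 without knockout control replicates 2, 6 and 7, and 120 with only knockout arrays fitted.

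Across the genes tested, the phenobarbital effects in both genotypes correlated with Pearson's r = 0.464 and Spearman's rho = 0.283. Genes are not independent replicates. Both effects were higher in 68 genes, where independence would give 4.1, and lower in 31, where it would give 3.99, while 3 changed in opposite directions against 8.11. Of the 577 genes changed in wild type, 450 had the same sign in knockout and 552 had a smaller effect there, with a median ratio of 0.242. Of the 325 changed in knockout, 260 had the same sign in wild type and 241 had a smaller effect there, with a median ratio of 0.566. Choosing genes by their change in 1 genotype makes the other look smaller, so neither ratio measures how far the effects differ. Without knockout control replicates 2, 6 and 7, r was 0.331.

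**Figure D2:**
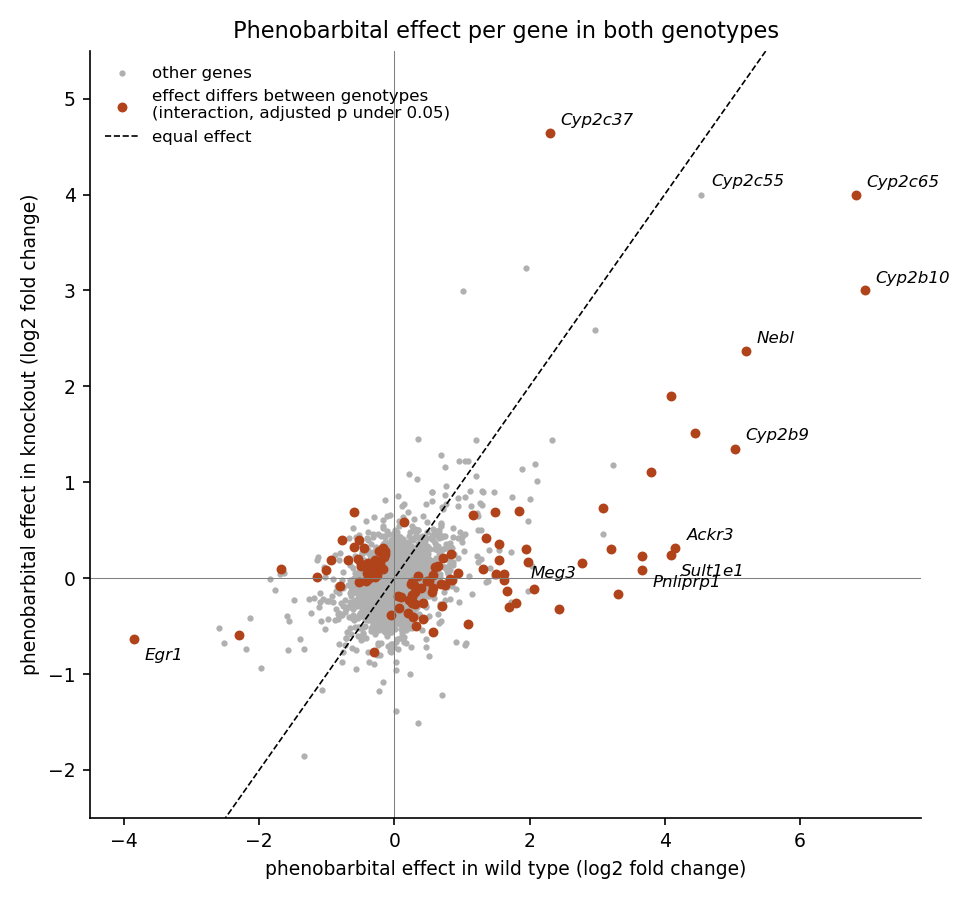
Phenobarbital effect per gene in wild type (x axis, log2 fold change) and in knockout (y axis, log2 fold change) for all 11579 genes tested. Coloured points are the 119 genes whose effect differed between the genotypes, and the dashed line marks equal effects; Cyp2c37 lies above it and Cyp2b10, Meg3 and Sult1e1 below it.

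Knockout and wild-type livers without phenobarbital were compared to see what the loss of beta-catenin changed by itself. Most perivenous genes fell. The ethanol-metabolizing Cyp2e1 went from 14.10 ± 0.093 to 9.05 ± 1.03 (n = 5 and 7; log2 change -5.05, SE 0.36, adjusted p = 1.63e-09). Glul (chromosome 1, 153899929 to 153909723) fell from 12.32 ± 0.13 to 8.81 ± 0.65 (log2 change -3.51, SE 0.27, adjusted p = 6.72e-09). Lect2 fell (-4.998, SE 0.38), the transcription factor Tbx3 (-4.27, SE 0.13), ornithine aminotransferase Oat (-4.22, SE 0.21), the gluconolactonase Rgn (-4.21, SE 0.45) and the vasopressin receptor Avpr1a (-4.14, SE 0.16). In all knockout control arrays Tbx3 was below the filter's level, against which its fall was 2.93. The Wnt target Axin2 fell (-0.79, SE 0.11, adjusted p = 1.81e-05), Cyp1a2 (-2.79, SE 0.18) and Cyp2c37 (-3.996, SE 0.35). Of 31 perivenous genes 26 fell and 0 rose (26 and 1 adjusted over the list alone), with a camera adjusted p = 3.55e-33, and 8.87e-08 with an estimated correlation. The list mean per array was 6.99 ± 0.12 in knockout and 9.04 ± 0.0889 in wild type (difference -2.05, exact permutation p = 0.00126).

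Periportal genes moved the other way and by less. Of 31, 9 rose and 1 fell (11 and 2 adjusted over the list alone), with a camera adjusted p = 0.019 and an adjusted p = 0.516 with an estimated correlation. Hsd17b13 (1.03, SE 0.14), Aldh1b1 (1.19, SE 0.18) and Cyp2f2 (0.27, SE 0.059, adjusted p = 0.00236) rose. Cyp2b10 and its paralog Cyp2b9 were already higher in untreated knockout, at 9.75 ± 0.98 and 7.60 ± 1.17 against 5.68 ± 0.39 and 4.01 ± 0.23 (log2 change 4.07 and 3.59, adjusted p = 1.18e-08 and 0.000103; 3.04 for Cyp2b9 against the filter's level). The Dlk1-Dio3 RNAs fell: Meg3 (-1.61, SE 0.11, 7 of 11 probe sets), Rian (-2.08, SE 0.18, 2 of 4 probe sets) and Mirg (-0.45, SE 0.069). Of that list 4 members were measured and 3 fell, also adjusted over the list alone, too few for a list test.

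Ctnnb1 itself (chromosome 9, 120933400 to 120960507) did not differ by the test, at 12.20 ± 0.024 in wild type and 12.25 ± 0.12 in knockout (0.048, SE 0.054, adjusted p = 0.524). None of its 3 probe sets passed the threshold, and their positions relative to the deleted exons are not given, so the arrays leave the deletion itself unmeasured. Ctnnb1 did not pass the test in the other comparisons either. Its log2 change was -0.13 (adjusted p = 0.284) with phenobarbital in wild type and -0.061 (0.596) in knockout. It was 0.12 (0.146) between the genotypes under phenobarbital, and 0.068 (0.852) for the interaction. Ctnnb1 passed in 1 of 35 alternatives with phenobarbital in wild type and in 2 of 35 between the genotypes under phenobarbital (over all alternatives 0.0403 to 0.65 and 0.0312 to 0.975).

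Markers of other liver cells were higher in knockout. Of 26 stellate cell and scar genes 22 rose (24 adjusted over the list alone), among them Postn (2.29, SE 0.27), Vim (2.20, SE 0.46) and collagen Col3a1 (2.12, SE 0.51). Of 22 endothelial markers 17 rose (19 adjusted over the list alone), with Lyve1 (2.44, SE 0.45), Plvap (1.25, SE 0.15) and the Wnt potentiator Rspo3 (0.94, SE 0.12). Of 22 macrophage markers 18 rose, also adjusted over the list alone, led by lysozyme Lyz2 (2.55, SE 0.63) and the monocyte receptor Ccr2 (2.28, SE 0.68; 2.21 against the filter's level). Camera adjusted p was 7.01e-14, 3.64e-09 and 1.78e-06 for these 3 lists, and adjusted p = 0.339, 0.388 and 0.547 with an estimated correlation. The knockout arrays differed widely from each other in these markers. The macrophage mean per array was 8.64 ± 0.94 in knockout and 7.20 ± 0.28 in wild type (exact permutation p = 0.0101), and the scar mean was 8.13 ± 0.59 and 6.84 ± 0.0864 (exact permutation p = 0.00126). Without knockout control replicates 2, 6 and 7, which had array weights of 0.492, 0.302 and 0.187, 2 macrophage, 18 scar and 18 endothelial markers were changed, and the adjusted p was 0.0999 for Lyz2 and 0.273 for Ccr2 (over all alternatives 0.00164 to 0.335 and 0.00235 to 0.273). The macrophage list still passed (camera adjusted p = 0.000256; over all alternatives 1.68e-09 to 0.547). For Ccr2 the 0.00235 came from the covariate for non-hepatocyte markers, where its log2 change was -1.091.

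A part of the interferon and acute-phase genes was higher in knockout too. Of 25 interferon genes 17 rose (24 adjusted over the list alone), with a camera adjusted p = 3.15e-06 and an adjusted p = 0.634 with an estimated correlation. Only 2 passed without knockout control replicates 2, 6 and 7. Without those arrays the adjusted p was 0.227 for the guanylate-binding Gbp2 (2.81, adjusted p = 0.0211), 0.217 for Gbp8 (3.50, adjusted p = 0.0162) and 0.121 for the class II antigen H2-Ab1 (2.90, adjusted p = 0.00667). Over all alternatives it ranged from 0.00936 to 0.312, 0.00705 to 0.217 and 0.00277 to 0.376. Of 28 acute-phase genes 9 rose (11 adjusted over the list alone), with a camera adjusted p = 5.59e-05 and an adjusted p = 0.53 with an estimated correlation. Without those 3 arrays 5 of them rose. The metallothioneins Mt1 (2.80, SE 0.42) and Mt2 (2.99, SE 0.57) led them. Bmper, a modulator of bone morphogenetic proteins, rose by 2.91 (SE 0.45; 2.37 against the filter's level, below which it was in wild type), and the fatty acid transporter Cd36 by 2.89 (SE 0.34). Of 20 p53 and growth arrest genes 8 rose and 2 fell (10 and 3 adjusted over the list alone), including Cdkn1a (1.75, SE 0.32), Btg2 (1.22, SE 0.21) and Gadd45b (0.96, SE 0.21). The list's camera adjusted p of 0.0325 became 0.659 with an estimated correlation, and 0.0632, 0.0634 and 0.0772 without knockout control replicate 6 or 7 or wild-type control replicate 5. Leaving out the 3 knockout control arrays together gave 0.25 (over all alternatives 0.00217 to 0.659). The interferon mean in knockout control replicates 1 to 7 was 8.89, 8.99, 7.63, 7.61, 7.59, 9.51 and 10.69, and the macrophage mean was 9.09, 9.41, 7.60, 7.66, 7.71, 9.75 and 9.23.

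Male-biased genes were lower in knockout: 12 of 23 fell (13 adjusted over the list alone), with a camera adjusted p = 4.21e-06 and an adjusted p = 0.517 with an estimated correlation. Without knockout control replicates 2, 6 and 7, 6 fell and the list median was -0.196 instead of -0.416. The steroid dehydrogenase Hsd3b5 fell from 12.56 ± 0.19 to 7.28 ± 3.80 (log2 change -5.28, SE 1.49, adjusted p = 0.0124) and ranged from 3.74 to 11.8 over the knockout controls. Its adjusted p was 0.201 without those arrays, and 0.00411 to 0.273 over all alternatives. The elongase Elovl3 (-3.35, adjusted p = 0.002) and Ugt2b38 (-2.29, adjusted p = 0.00609) also fell, the latter at an adjusted p = 0.0554 without those arrays (0.00157 to 0.607 over all alternatives). For Elovl3 the adjusted p was 0.000492 to 0.778 over all alternatives. Of 24 bile acid genes 9 fell (11 adjusted over the list alone), with a camera adjusted p = 6.69e-06 and an adjusted p = 0.484 with an estimated correlation. Without those arrays 5 fell, and the list median was -0.127 instead of -0.361. The uptake carrier Slco1b2 (-1.73, SE 0.18), Cyp27a1 (-1.36, SE 0.18) and Cyp7b1 (-1.35, SE 0.32) were among them. Slco1b2 and Cyp27a1 were also in the perivenous list. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell (-0.96, adjusted p = 0.035). That call ended without any 1 of knockout control replicates 6 and 7 and wild-type control replicates 2 and 3 (adjusted p 0.0736 to 0.122). Without the same 3 arrays its log2 change was -0.592 (adjusted p = 0.236), and with only the control groups the adjusted p was 0.0909 (over all alternatives 0.0164 to 0.61). Of 34 fatty acid oxidation genes 12 fell and 2 rose (14 and 3 adjusted over the list alone), with a camera adjusted p = 0.00129 and an adjusted p = 0.659 with an estimated correlation. That call ended without the same 3 arrays: 5 fell and 3 rose, with a median of -0.0219 instead of -0.168 (adjusted p = 0.125; over all alternatives 0.000344 to 0.659). The pyruvate dehydrogenase kinase Pdk4 fell (-1.66, SE 0.24). Cyp2c55 (0.21, adjusted p = 0.65), Cyp3a11 (-0.022, 0.728), Cyp2c29 (-1.06, 0.0806), Ccnd1 (0.67, 0.421) and Mki67 (1.30, 0.0617) did not pass the test. The last 3 passed in 4, 1 and 4 alternatives (over all alternatives 0.0336 to 0.913, 1.35e-05 to 0.854 and 0.0271 to 0.492). Ccnd1 passed only with the covariate for non-hepatocyte markers, and there in the opposite direction (log2 change -2.221). Among the genes named as changed in this comparison, arrays overlapped for Gadd45b, Cyp2f2, Cyp7a1, Pdk4 and Ugt2b38.

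The genotypes differed in 3239 genes without phenobarbital, 1963 higher and 1276 lower in knockout, and 426 rose and 103 fell at least 2-fold. As deposited 60.6% of the changed genes were higher, against 50.4% after quantile normalization and 36.4% after median centring, so the direction of the majority is not settled. In 1379 of all genes the arrays did not overlap, which chance gives for 0.25%, and 1349 of them were changed. Without knockout control replicates 2, 6 and 7 the count was 1546, and with only the control arrays fitted it was 2068.

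**Figure D3:**
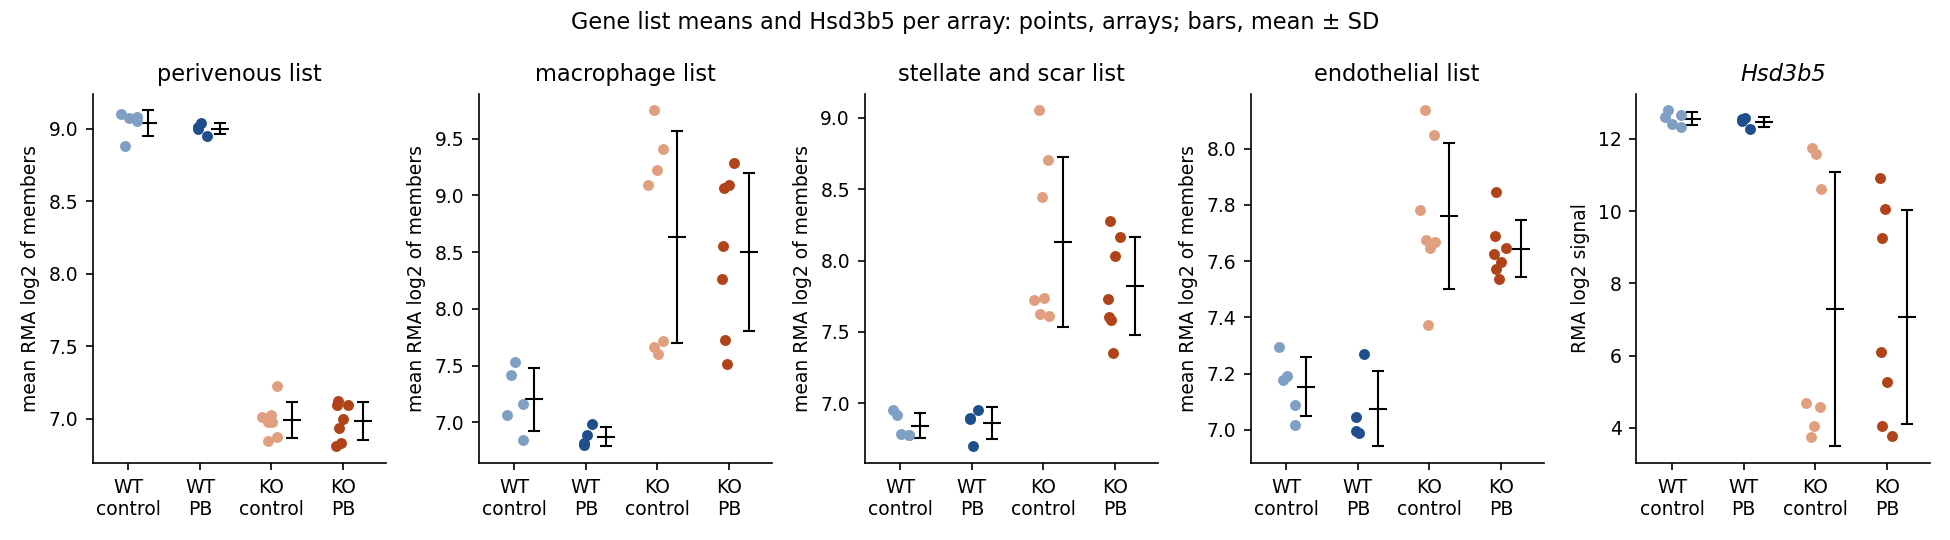
Mean RMA log2 signal of the members of 4 gene lists and the signal of Hsd3b5 (y axes) in every array of the 4 groups. Points are arrays and bars give mean ± SD; the perivenous mean was 9.04 and 6.99 in wild type and knockout without phenobarbital, and Hsd3b5 ranged from 3.74 to 11.8 in the knockout controls.

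Under phenobarbital the perivenous difference between the genotypes persisted. Cyp2e1 was 14.11 ± 0.049 in wild type and 7.67 ± 0.53 in knockout (n = 4 and 7; log2 change -6.45, SE 0.38, adjusted p = 6.33e-11). Lect2 was lower (-5.54, SE 0.41), the potassium channel Kcnk1 (-5.31, SE 0.42), the vitamin C synthesis gene Gulo (-4.56, SE 0.21), Rgn (-4.53, SE 0.48), Oat (-4.22, SE 0.23) and the carboxylate transporter Slc13a3 (-4.03, SE 0.28). Glul (-3.10, SE 0.29), the ammonium transporter Rhbg (-1.50, SE 0.14), Cyp1a2 (-2.19, SE 0.19) and Axin2 (-0.73, SE 0.11) were lower too. Of 31 perivenous genes 25 were lower and 0 higher (26 and 1 adjusted over the list alone), with a camera adjusted p = 1.21e-31, and 8.87e-08 with an estimated correlation. Of 31 periportal genes 12 were higher and 2 lower (13 and 2 adjusted over the list alone), with Aldh1b1 (2.36, SE 0.20) and Cyp2f2 (0.38, SE 0.063) higher. The list's camera adjusted p was 0.00901, and the adjusted p = 0.476 with an estimated correlation.

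Meg3 was lower in knockout under phenobarbital (-3.79, SE 0.12, adjusted p = 5.3e-16), in all 11 probe sets, Rian (-3.28, SE 0.19) and Mirg (-0.57, SE 0.074). Cyp2c65 (-3.01, SE 0.27), Cyp2b13 (-3.19, SE 0.48), Sult1e1 (-3.50, SE 0.29), Sult1c2 (-1.54, SE 0.21), Abcc4 (-1.47, SE 0.38) and Prom1 (-2.24, SE 0.35) were lower as well, with overlapping arrays for Cyp2b13 and Abcc4. Of 37 CAR targets 14 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 4.39e-05, and adjusted p = 0.11 with an estimated correlation). Cyp2b10 itself reached nearly equal levels, 12.64 ± 0.048 and 12.76 ± 0.17 (log2 change 0.11, SE 0.35, adjusted p = 0.836). Cyp2c55 (-0.33, adjusted p = 0.514), Cyp2c29 (0.034, 0.966) and Cyp3a11 (-0.024, 0.723) did not differ by the test, nor did Cyp7a1 (-0.83, 0.0922), Ccnd1 (1.54, 0.0858) or Mki67 (0.86, 0.262). Cyp7a1 and Ccnd1 passed with only the phenobarbital groups fitted (adjusted p = 0.0291 and 0.043; over all alternatives 0.0193 to 0.569 and 0.0102 to 0.278).

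Of 21 cholesterol synthesis genes 10 were lower in knockout under phenobarbital (13 adjusted over the list alone), with Hsd17b7 (-1.12, SE 0.16), Mvd (-0.93, SE 0.21) and Fdps (-0.89, SE 0.18) changed most. The camera adjusted p was 1.59e-06, and the adjusted p = 0.499 with an estimated correlation. Without phenobarbital 1 gene of this list was higher and 1 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.325, fry mixed adjusted p = 0.119). Tff3, which fell with phenobarbital in wild type, was higher in knockout by 4.44 (SE 0.48). Egr1 was higher by 3.20 (SE 0.42), the acute-phase amyloids Saa2 by 4.09 (SE 1.09) and Saa1 by 3.13 (SE 0.58), Mt1 by 3.45 (SE 0.45) and Mt2 by 3.07 (SE 0.61). Gbp8 (3.77, adjusted p = 0.0178) and the nutrient sensor Rragd (3.07, adjusted p = 0.0148) were higher too. Over all alternatives the adjusted p ranged from 0.000775 to 0.523 for Saa2, 0.000836 to 0.998 for Gbp8 and 0.000579 to 0.827 for Rragd. Of 28 acute-phase genes 10 were higher (14 adjusted over the list alone; camera adjusted p = 1.92e-05, and adjusted p = 0.517 with an estimated correlation).

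Macrophage, scar and endothelial markers were higher in knockout under phenobarbital as well: 17 of 22, 17 of 26 and 18 of 22 (19, 22 and 19 adjusted over the list alone). Camera adjusted p was 1.12e-07, 7.12e-09 and 3.61e-09, and adjusted p = 0.517, 0.484 and 0.388 with an estimated correlation. Examples were cathepsin Ctss (2.50, SE 0.53), complement C1qb (2.22, SE 0.48), Pdgfra (1.66, SE 0.20), the retinyl ester synthase Lrat (1.66, SE 0.14) and Rspo3 (1.12, SE 0.12). The macrophage mean per array was 8.50 ± 0.70 in knockout and 6.87 ± 0.0842 in wild type (difference 1.63, exact permutation p = 0.00606). Hsd3b5 was lower (-5.41, SE 1.60, adjusted p = 0.0182), and again spread widely over the knockout arrays (7.06 ± 2.96). Its adjusted p ranged from 0.000988 to 0.989 over all alternatives.

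Under phenobarbital the genotypes differed in 2708 genes, 1635 higher and 1073 lower in knockout, with 274 rises and 124 falls of at least 2-fold. The share of higher genes was 60.4% as deposited and 41.5% after median centring, so the direction of the majority again depended on the scaling. In 2441 of all genes the arrays did not overlap (0.61% by chance), and 2007 of them were changed. The count was 1796 without wild-type phenobarbital replicate 3 and 4488 with 1 weight per group.

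The interaction asked for which genes the phenobarbital effect depended on beta-catenin. It passed the test in 119 genes, and in 100 of them the effect was larger in wild type. Pnliprp1, a lipase-related gene, rose from 3.10 ± 0.10 to 6.77 ± 0.12 in wild type and was 3.14 ± 0.12 and 3.22 ± 0.16 in knockout (interaction -3.59, SE 0.11, adjusted p = 1.36e-15). Meg3 was similar, at 2.07 in wild type and -0.11 in knockout (interaction -2.18, SE 0.16, adjusted p = 1.74e-08), as was Sult1e1, at 4.09 and 0.24 (interaction -3.86, SE 0.40, adjusted p = 3.49e-06). Pnliprp1 and Sult1e1 were below the filter's level in all wild-type controls, so the size of these interactions is uncertain. Pnliprp1 was below it in all knockout arrays too. The same limit holds for Cyp2b9 in wild-type controls and Cyp2c65 in both control groups, whose interactions were -3.69 and -2.834. Ackr3 (-3.84, adjusted p = 0.000351), Serpinb1a (-3.44, adjusted p = 4.92e-07) and Lratd1 (-3.47, adjusted p = 1.49e-07) also had interactions below 0. For Cyp2b10 the interaction was -3.95 (adjusted p = 4.25e-05), with different levels before treatment (5.68 ± 0.39 and 9.75 ± 0.98) and similar ones after it. Egr1 fell in wild type (-3.85) and had a log2 change of -0.64 in knockout (adjusted p = 0.401; interaction 3.22, SE 0.57, adjusted p = 0.00456).

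Further interactions above 0 were those of Tspyl4 (1.77, adjusted p = 0.00619), Dnaic1 (1.70, adjusted p = 0.00308), the endosomal GTPase Rab5c (1.29, adjusted p = 0.000153), and Lgr5 (1.09, adjusted p = 0.0035). Tnfrsf19 had a negative one (-1.58, adjusted p = 0.000361), but it was below the filter's level in all knockout arrays, so its size is uncertain. Several calls depended on single arrays. Cyp2c37 rose more in knockout (2.34, adjusted p = 0.0214), with adjusted p of 0.0534 and 0.0512 without wild-type phenobarbital replicate 1 or 3 (over all alternatives 0.00365 to 0.0692). It rose from 10.99 ± 0.472 to 13.29 ± 0.0817 in wild type and from 6.993 ± 0.945 to 11.64 ± 0.451 in knockout. The larger rise in knockout thus began at a lower level, and Cyp2c37 remained lower there under phenobarbital (log2 change -1.65). Rian (-1.20, adjusted p = 0.0211) had adjusted p of 0.0537 and 0.0602 without wild-type phenobarbital replicates 1 or 2. Cyp2b9 (-3.69, adjusted p = 0.0271) had 0.0507 to 0.0761 without wild-type control replicate 2 or phenobarbital replicates 1, 2 or 3. Cyp2b13 (-2.94, adjusted p = 0.0277) had 0.0521 to 0.0907 without wild-type control replicates 1 or 2 or phenobarbital replicates 1, 2 or 3. Aldh1b1 (1.17, adjusted p = 0.0284) lost its call without wild-type control replicates 1 to 4 or phenobarbital replicates 1, 3 or 4 (0.0512 to 0.0929). For Rnd1 (1.12, adjusted p = 0.0279) these were wild-type control replicates 1, 2 and 4 and phenobarbital replicates 1 to 4 (0.0518 to 0.0673). For Slc1a2 (1.17, adjusted p = 0.0302) they were wild-type control replicates 1 and 5, wild-type phenobarbital replicates 1 to 4, knockout control replicate 2 and knockout phenobarbital replicates 2 and 6 (0.05 to 0.0933), and it was 0.0717 without knockout control replicates 2, 6 and 7 (over all alternatives 0.0019 to 0.0933).

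By list, 6 of 37 CAR targets had an interaction below 0 and 1 above it (8 and 2 adjusted over the list alone), with a camera adjusted p = 0.000151 and an adjusted p = 0.146 with an estimated correlation. Of 19 female-biased genes 4 had a negative one (5 negative and 1 positive adjusted over the list alone; camera adjusted p = 0.00237, and adjusted p = 0.459 with an estimated correlation). Both cholesterol synthesis and lipogenesis had 0 changed members (7 and 3 lower adjusted over the list alone), with list medians of -0.45 and -0.21. Camera adjusted p was 1.51e-07 and 0.000216, and adjusted p = 0.476 and 0.547 with an estimated correlation, while the fry mixed adjusted p was 0.0334 and 0.0655. Leaving out knockout control replicates 2, 6 and 7, 11 and 3 members had a negative interaction, with list medians of -0.692 and -0.386. The interaction did not pass the test for Cyp2c55 (-0.54, adjusted p = 0.77), Cyp2e1 (-1.40, 0.273), Cyp2c29 (1.09, 0.6), Cyp1a2 (0.59, 0.389), Glul (0.41, 0.807) or Axin2 (0.069, 0.943). Nor did it for Cyp3a11 (-0.0027, 0.995), Oat (-0.0012, 1), Cyp2f2 (0.12, 0.705), Cyp7a1 (0.13, 0.97), Ccnd1 (0.87, 0.818) or Mki67 (-0.45, 0.911). Cyp2e1 and Ccnd1 passed in 2 and 1 alternatives (over all alternatives 0.0377 to 0.421 and 0.00398 to 0.9).

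Of the 119 genes, 98 changed with phenobarbital in wild type (58 up and 40 down), 30 changed in knockout and 12 in both. In 77 the signs of both effects were opposite, whether or not the effects passed the test. Over all genes tested, only 3 were changed in opposite directions, so most of the 77 include an effect that did not pass. Choosing genes by a difference between the effects also favours opposite signs. Among the 119 genes, 60 differed between the genotypes without phenobarbital and 92 with it. The count was 70 without wild-type phenobarbital replicate 3, 288 without knockout control replicates 2, 6 and 7, and 397 with array weights.

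The change caused by the knockout was also set against the phenobarbital effect in wild type, which asks whether losing beta-catenin resembles the treatment. Across genes r was 0.0826 and rho 0.101. Both comparisons share the wild-type controls, which alone gave a mean r of 0.509 and a covariance of 0.0137 in simulated groups without any effect, against 0.0111 observed. With the controls split between the comparisons, r was 0.0331 and the covariance 0.00455 over 10 splits. In both, 61 genes were higher and 89 lower, and 75 changed in opposite directions. No count expected with shared controls was computed.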

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

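The tests of shares between marker lists, of members without the 3 arrays, of the residual perivenous level and of perivenous minus periportal genes were chosen only after the result was seen. The other splits of the samples and the test of immediate-early genes were fixed beforehand, though Fos was left out of the latter because it had already been seen.

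Other splits of the same arrays were counted for each comparison, with 100 splits each and the real one included. For phenobarbital in wild type the real split (577 genes) was matched by 1 split, itself, and the highest other gave 169. With 100 splits the share cannot go below 1 in 100, so chance is unlikely to give that count but is not excluded. Nor can the splits tell the treatment from another difference shared by the treated samples. For knockout against wild type without phenobarbital 2 splits reached 3239 genes, and the highest other gave 3894, more than the real one. Under phenobarbital 1 split, the real one, reached 2708, with a highest other of 1153, and 4 splits reached the 119 genes of the interaction, with a highest other of 262. In these 3 the share was under the bound of 0.05 set beforehand. For the interaction it was close to that bound, and with 100 splits drawn its sampling error reaches past it, so chance is not firmly excluded there. The interaction splits mixed treated and control arrays within each genotype, which also removes a phenobarbital effect that both genotypes share. The share for the interaction thus does not test a difference between the 2 effects by itself. Without phenobarbital the higher count of another split also points to a structure of the samples. For phenobarbital in knockout 7 splits gave at least 325 genes, with a highest other of 3870, so chance was not excluded for the count. A split that calls several times the real count points to a structure among the knockout arrays.

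The phenobarbital effect differed between the genotypes, by the interaction test, in 27 named genes. The difference, knockout minus wild type in log2 units, was below 0 for the P450 genes Cyp2b10 (-3.95), Cyp2b9 (-3.69), Cyp2b13 (-2.945) and Cyp2c65 (-2.834), and for Sult1e1 (-3.856), Ackr3 (-3.837), Pnliprp1 (-3.586), Lratd1 (-3.471) and Serpinb1a (-3.439). It was also below 0 for Prom1 (-2.89), Nebl (-2.832), Kcnk1 (-2.617), Abcc4 (-2.351), Meg3 (-2.182), Gadd45b (-1.817), Tnfrsf19 (-1.582), Rian (-1.204) and Nipbl (-0.4766). It was above 0 for Egr1 (3.218), Cyp2c37 (2.344), Tspyl4 (1.766), Dnaic1 (1.704), Rab5c (1.29), Aldh1b1 (1.173), Slc1a2 (1.165), Rnd1 (1.12) and Lgr5 (1.093). By camera it also differed for CAR targets (median -0.141), cholesterol synthesis (-0.446), lipogenesis (-0.212), female-biased genes (-0.114) and the scar list (-0.319). With an estimated correlation none of these 5 lists passed (adjusted p = 0.146, 0.476, 0.547, 0.459 and 0.754). The scar call also ended without knockout control replicate 2, 6 or 7 or knockout phenobarbital replicate 2 (adjusted p = 0.0971, 0.146, 0.0563 and 0.08).

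Single arrays far from the rest of their group were found for 11 combinations of a named gene and a group. They were Cyp2b13 in knockout phenobarbital replicate 5 (8.915), Dnaic1 in knockout control replicate 1 (4.507), Cyp2e1 (13.94), Rab5c (8.273) and Tspyl4 (9.006) in wild-type control replicate 3, and Smc6 in wild-type control replicate 4 (7.809). The others were Slco1b2 in replicate 7 of both knockout groups (10.3 without and 10.81 with phenobarbital), Aldh1b1 in wild-type phenobarbital replicate 2 (8.917), Hsd17b13 in wild-type control replicate 1 (8.214) and Gadd45b in knockout control replicate 7 (8.102). Chance marks about 1 in 20 groups, or 22 of the 440 tested.

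The first pattern weighed was the higher level of macrophage, scar and endothelial markers in knockout liver. A uniformly larger share of all non-hepatocyte RNA would raise the lists alike only if background and hepatocyte signal compressed their log2 changes alike, which was not tested. Of 4 exact permutation tests of macrophage or scar minus endothelial means, 3 passed an adjusted threshold (adjusted p = 0.0253, 0.0253 and 0.0404). Macrophage minus endothelial without phenobarbital did not (exact permutation p = 0.0707). The lists thus did not all rise alike, but because of that compression these tests cannot decide on a uniform share. Most calls of single macrophage markers in the controls depended on 3 knockout control arrays of low weight: 2 members instead of 18 were changed without them, with fewer arrays compared. The 3 were not the only high controls. Knockout control replicate 1, which stayed in, had a macrophage mean of 9.088, against 7.604 to 7.714 in replicates 3 to 5. The macrophage list still passed, with a median of 0.902 instead of 1.58 (camera adjusted p = 0.000256; over all alternatives 1.68e-09 to 0.547). The 3 arrays do not account for the scar and endothelial calls, of which 36 members were changed against 39, nor the 17 macrophage markers higher under phenobarbital, where other arrays were compared. An effect of the knockout on these cells, such as injury or inflammation, may underlie the remainder. That is a hypothesis found in these data, and it was not tested.

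The second pattern was the fall of perivenous genes in knockout. Dilution of hepatocyte RNA by other cells would lower periportal genes alike, but perivenous minus periportal means differed between the genotypes (exact permutation p = 0.00126, the smallest that 792 splits can give). Residual expression could come from perivenous hepatocytes that escaped recombination. The 26 fallen genes had a median pairwise correlation of 0.0533 over 14 knockout arrays, at percentile 89.4 of 10000 random lists. The bound written for this test was wrong, since livers with an equal residual share give no correlation, so that explanation stays open. Loss of beta-catenin as designed is the biological candidate explanation for the fall.

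The third pattern was the fall of Egr1 with phenobarbital in wild type (log2 change -3.85). Egr1 is an immediate-early gene that responds to handling and dissection. The median change of 21 other immediate-early genes was -0.0277, with 11 negative and 0 changed in either direction. The lowest change was -0.607 (SE 0.24), for Btg2. These values argue against sampling or handling that lowered these 21 genes about as far as Egr1. With an SE of up to 0.435, for Jun, smaller falls of single genes are not excluded. Fos is not among the 21, since it had been seen before, so the test does not cover it. An effect of phenobarbital on Egr1 that depends on beta-catenin (interaction 3.218) remains a hypothesis. A handling effect that reached Egr1 but no other gene of that list was not tested.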

How the results depend on the processing

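The fit with 1 weight per group, the fit without knockout control replicates 2, 6 and 7 and the covariate for the level of non-hepatocyte markers were chosen only after the result was seen. The cause was not tested unless stated.

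Of 181 changed results for named genes, all 181 kept direction and call after quantile normalization, median centring and a trended and robust prior. The 167 that passed the filter at the 60th percentile kept them too. Calls ended for 2 without a filter, 3 of 178 with the mean of probe sets, 7 with array weights, 9 of 161 with only the compared groups, 4 with 1 weight per group and 13 without the 3 arrays. With the covariate 24 ended and 11 turned, and leaving out single arrays ended 16 at least once. Of 58 list calls, 57, 56, 55, 54 and 58 kept theirs with no filter, quantile normalization, median centring, the mean of probe sets and a trended prior. Only 8 passed with an estimated correlation, 43 with fry, 48 with array weights, 48 without the 3 arrays and 30 with the covariate.

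Testing every probe set, which tests more items, gave 937 and 705 changes with phenobarbital in wild type and knockout, 5260 and 4376 between the genotypes without and with it, and 245 for the interaction. Array weights gave 1652 and 505 with phenobarbital in wild type and knockout, 4462 between the genotypes under it and 397 for the interaction, and 1 weight per group gave 1350, 119, 4488 and 180 in the same order. Only the compared groups gave 998 and 120 with phenobarbital and 2068 between the genotypes without it. A 2-fold minimum left 87, 22, 529, 398 and 40, by its construction. The replicate number as a block gave 1945 and 1632 between the genotypes and ended 23 gene calls. Only 2 of 5 arrays correlated best with their own number between the control groups, and 0 elsewhere. Yet 3 of 5 same-numbered pairs there, and 2 of 7 with phenobarbital in knockout, had a correlation above 0.1. Whether the numbers pair the arrays is thus not settled.

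Without the 3 knockout control arrays the counts were 829 for phenobarbital in knockout, 1546 between the genotypes without phenobarbital and 288 for the interaction, with fewer arrays compared. Only controls were left out: knockout phenobarbital replicates 4, 5 and 7 stayed, with high macrophage means of 9.068, 9.288 and 9.095. For phenobarbital in knockout and the interaction, this fit thus set selected controls against unselected treated arrays, which can itself shift counts and lists. The correlation of the phenobarbital effects became 0.331. The direction of the camera test, which compares a list with all other genes, turned for several lists. These passed with or without the 3 knockout control arrays (list medians without them in brackets). With phenobarbital in knockout these were bile acids (-0.0886), proliferation (0.326), interferon (0.395), macrophages (0.578), cholangiocytes (0.32), scar (0.13) and fetal genes (0.401), and in the interaction p53 (0.225), cholangiocytes (0.282) and scar (0.13). The medians of bile acids and proliferation in knockout, and of p53 and cholangiocytes in the interaction, kept their sign. Of 145 list medians 30 changed sign, 8 of them for lists that passed in either fit, including phase I enzymes (0.04) and urea and ammonia (0.0231) between the genotypes without phenobarbital. In knockout, array weights turned the camera direction of bile acids (-0.0956) and interferon (0.125), and leaving out knockout control replicate 6 turned that of proliferation (0.186), whose median ranged down to -0.107 without other single arrays.

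The covariate differs between the genotypes by itself, so it takes out part of their difference by construction. It is the mean of the macrophage, lymphocyte, neutrophil, cholangiocyte, scar and endothelial list means. Sign changes of these lists and of their members, such as Lyz2, Ccr2, Vim and Epcam, are thus in part built in. The covariate gave 967, 814, 1270, 1744 and 290 changed genes. Between the genotypes without phenobarbital it turned Gbp8 (-1.325), H2-Ab1 (-0.5866), Gbp2 (-1.057), Lyz2 (-0.4746), Ccr2 (-1.091), Vim (-0.004157), Col3a1 (-0.2295), Cd24a (-0.04715), Epcam (-0.3165), Ccnd1 (-2.221) and Hsd3b5 (1.617), and under phenobarbital Gbp2 (-0.04054). The camera direction of lists that passed in either fit turned too, with medians under the covariate in brackets. Without phenobarbital these were phase I enzymes (0.0428), bile acids (0.0212), fatty acid oxidation (0.101), Nrf2 (-0.313), proliferation (-0.551), p53 (-0.105), acute phase (-0.106), interferon (-0.545), male-biased (0.234), macrophages (-0.355), cholangiocytes (-0.253) and fetal genes (-0.287). Under phenobarbital they were bile acids (0.0415), Nrf2 (-0.202), proliferation (-0.499), interferon (-0.392), male-biased (0.0761) and fetal genes (-0.288). For phenobarbital in knockout they were bile acids (-0.0554) and proliferation (0.211), whose medians kept their sign, and interferon (0.0975), macrophages (0.356) and fetal genes (0.273).

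Leaving out each array gave 325 to 698 and 212 to 456 changed genes with phenobarbital in wild type and knockout, 2571 to 3604 and 1796 to 3196 between the genotypes without and with it, and 70 to 151 for the interaction. The lowest counts were those without wild-type phenobarbital replicate 3 (325, 1796 and 70), knockout phenobarbital replicate 1 (212) and wild-type control replicate 2 (2571), and without wild-type phenobarbital replicate 1 it was 374 in wild type. Ctnnb1 ranged from 0.01909 to 0.07216 between the genotypes, the list calls from 54 to 65, and r from 0.419 to 0.484 between the phenobarbital effects and from 0.0535 to 0.114 for genotype and phenobarbital.

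On simulated arrays, 74.6% of changes of 0.5 log2 units were recovered for phenobarbital in wild type, 79.1% in knockout, 71.6% and 76.1% between the genotypes and 52.2% for the interaction. Of the calls, 4.04%, 4.19%, 8.41%, 6.19% and 5.38% were false. With a separate SD per group 14.1% were false for phenobarbital in knockout and 13.7% between the genotypes without it. Noise was drawn independently for each gene, in a single run per setting, so these shares need not hold where genes vary together. Signal near background limits genes under the filter, of which 6614 were left out.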

Other observations

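The fit without knockout control replicates 2, 6 and 7 and the covariate for non-hepatocyte markers were chosen only after the result was seen. The lists in this part were fixed beforehand.

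Of 24 proliferation genes 3 rose and 1 fell in knockout without phenobarbital (1 and 1 adjusted over the list alone; camera adjusted p = 0.0433, and adjusted p = 0.786 with an estimated correlation). That call ended without knockout control replicate 2 or 6 or wild-type control replicate 1, 3, 4 or 5 (adjusted p from 0.0525 to 0.207). Of 11 cholangiocyte markers 3 rose there (4 adjusted over the list alone; adjusted p = 0.0269, and 0.659 with an estimated correlation), and the call ended without knockout control replicate 2 or 6 (0.0703 and 0.0651). Of 19 fetal and tumour genes 3 rose, also adjusted over the list alone (adjusted p = 0.0489, and 0.679 with an estimated correlation). Leaving out any 1 of knockout control replicates 2, 6 and 7, wild-type control replicates 1, 2 and 5 and wild-type phenobarbital replicates 1 and 2 ended it (0.0505 to 0.0971). Without knockout control replicates 2, 6 and 7 together, none of these 3 lists passed (adjusted p = 0.882, 0.483 and 0.462). Over all alternatives it was 1.96e-06 to 0.882, 0.00643 to 0.659 and 0.00406 to 0.679. The 1.96e-06 came from the covariate for non-hepatocyte markers, under which the proliferation list was lower in knockout (median -0.551). The cholangiocyte and fetal lists turned there too (medians -0.253 and -0.287).

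Of 10 lymphocyte markers 5 rose and 1 fell in knockout without phenobarbital (7 and 1 adjusted over the list alone; camera adjusted p = 0.07), and of 6 neutrophil markers 3 rose, also adjusted over the list alone (adjusted p = 0.0689). Leaving out the 3 arrays, 1 lymphocyte and 2 neutrophil markers rose. Of 25 genes of glucose metabolism 5 fell without phenobarbital (3 adjusted over the list alone; adjusted p = 0.127; 1 fell and 2 rose without the 3 arrays), and 7 fell and 1 rose under it, also adjusted over the list alone (adjusted p = 0.00901, and 0.564 with an estimated correlation). Of 24 genes of the unfolded protein response 2 rose and 1 fell without phenobarbital (1 and 1 adjusted over the list alone; adjusted p = 0.989). Of 18 circadian clock genes 0 changed there by limma, also adjusted over the list alone (adjusted p = 0.317, fry mixed adjusted p = 0.323).

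Of 9 genes of other tissues 3 were lower in knockout under phenobarbital (4 adjusted over the list alone; camera adjusted p = 0.00901, and 0.517 with an estimated correlation). Of the blood list 2 genes were measured, too few for a list test, and 1 was lower under phenobarbital. Of 21 genes of urea and ammonia metabolism 8 fell and 1 rose in knockout without phenobarbital, also adjusted over the list alone (camera adjusted p = 0.00128, and 0.517 with an estimated correlation). Leaving out the 3 arrays, 5 fell and 1 rose, and the median turned from -0.0687 to 0.0231. Under phenobarbital their median was 0.0236 and their mean -0.446, so the signs differed (adjusted p = 0.075).

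Between the genotypes without phenobarbital, 12 of 39 conjugation enzymes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000105, and 0.146 with an estimated correlation). Of 24 transporters 7 fell and 2 rose (9 and 3 adjusted over the list alone; adjusted p = 0.0412, and 0.484 with an estimated correlation). That call ended without knockout control replicate 7 (0.0702) or wild-type control replicate 4 (0.0818). For 50 phase I enzymes, 14 fell and 10 rose (15 and 10 adjusted over the list alone; adjusted p = 0.0293, and 0.634 with an estimated correlation), and without the same arrays the adjusted p was 0.0971 and 0.0503. In the fit without knockout control replicates 2, 6 and 7, 10 fell and 8 rose, and the median turned from -0.188 to 0.04 (adjusted p = 0.206; over all alternatives 0.0152 to 0.868). Without these 3 arrays 7 conjugation enzymes fell, and 4 transporters fell and 3 rose. With phenobarbital in knockout, cholesterol synthesis had 0 changed members (4 lower adjusted over the list alone), with a median of -0.19, a camera adjusted p = 5.18e-05, and 0.547 with an estimated correlation. Without the 3 arrays 12 members fell, with a median of -0.41.

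Where a gene had several probe sets, another one changed the other way for 2 of 378 changed genes with phenobarbital in wild type, 1 of 194 in knockout, 52 of 1993 and 28 of 1714 between the genotypes and 0 of 77 for the interaction. The first principal component held 58.6% of the variance between arrays and the second 9.92%.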
